A study of Saccharomyces cerevisiae and Mus musculus with 38 samples.

How the data were processed

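Yeast and mouse libraries were analysed from the deposited processed tables alone, without the reads. The labels name 14 NET-seq libraries (4 without rapamycin, 3 at 15 min, 3 at 30 min and 4 at 60 min), 22 mRNA libraries with 1 per group, and 2 ChIP-seq libraries of tagged Hsf1. Per the labels' protocols total RNA was extracted with RNeasy kits and libraries were made with Illumina TruSeq. Per the submitters' processing notes Bowtie, Cufflinks and Cuffdiff were used with the genome builds sacCer3 and mm10, and no versions are given in the sources used here.

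The mRNA tables hold the authors' FPKM values, named so per the file headers for mESC and taken so from the values and from Cufflinks in the submitters' processing notes for the other tables. The deposited NET-seq table has the layout of a Cuffdiff result per the file headers, with a group value at each of a pair of successive times, the authors' log2 fold change, and the authors' p-value and q-value. The deposited ChIP-seq table gives for each peak the authors' count of reads (tags), the authors' fold enrichment, which is a ratio over background, and the authors' score, derived from a p-value. Both ChIP-seq peak lists are headed as basal, so neither was assigned to heat shock, and their values served only to describe and rank peaks within a list.

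Main choices were fixed before the data were examined, among them 18 yeast and 19 mouse gene lists. Replicate values for NET-seq, on which a test of its own per gene and a test of gene lists had been planned, are not given in the sources used here, so the authors' calls at a q below 0.05 were used for successive times, and lists were described by percentile. For each pair of mRNA libraries the log2 ratio was computed after adding 1 to each FPKM. A gene was compared when the larger value was at least 10, counted as higher or lower at 2-fold or more, and left out when listed at 0 in a library. Each list was described by the percentile of its median log2 change among 10000 random lists of the same size, matched on mean expression in 20 bins, with the middle 95 percent as the bound. Where the median of all genes lay more than 0.1 from 0, gene and list values are given relative to it, with the treated FPKM rescaled by the shift before 1 was added. With 1 library per group no p-value was computed, and differences between responses were not tested. NET-seq times of 30 and 60 min against 0 min were described by the same rule of 2-fold and 10 on the deposited group values. Expected overlaps are products of the group sizes over the genes that could be in both.

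The text names genes by a rule set in advance: the 10 with the largest rise and the 10 with the largest fall in each comparison, members of the fixed lists, the perturbed genes, and the peaks with the highest values. Genes listed at 0 and short RNAs were not to be named, and the condition on replicates in that rule could not be applied to NET-seq group values. TRP1, STE2, STE3, the mating pheromone genes, FPR1, RPL13B, Phlda2, Grb10, Cdkn1c, Dlk1, Meg3, Igf2, H19, Clk4, Dpp7, D4Wsu53e, Dnmt3a, Ptprf, Tle4, DFR1, FRE4 and the called genes PCD1, RIM4, YKR075C, MLH3, TUS1 and LST8 were picked after their values were seen wherever they fall outside this rule.

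Some table entries were left out. In the yeast mRNA tables, loci that share the stem of their identifier with another locus, loci with several entries, and entries holding a sum could not be tied to a single gene, which left 4648 genes of 5494 entries in the separate Hsf1-AA experiment and 5085 of 5694 in the time course and the TPK-as tables. The labels of 170 of the loci sharing a stem were checked by correlation across loci with the 0 min library, loci not being independent replicates. Over these loci it was 0.97 for TPK-as control and 0.89 for TPK-as heat shock, but -0.07 for TPK-as 1NM-PP1 and -0.04, -0.06 and -0.08 for TPK-as msn2/4 control, heat shock and 1NM-PP1, while over other loci it was 0.94, 0.79, 0.57, 0.94, 0.81 and 0.73 in that order. In those 4 libraries the values of these loci do not go with the labels of the 0 min library. Which labels are wrong cannot be told from this check, and the loci were left out of every yeast mRNA table. The MEF table holds 22716 genes, and for mESC 25998 entries were summed to 21471 genes, 3865 of which have several. No column of another sample was used or left over.

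Read totals are not given in the sources used here. In the mouse tables a relative depth was estimated from log2 ratios to WT control, in the 8 percent of entries with the lowest summed values. The offset where these ratios gathered most was taken as the relative worth of a read. The relative depth was 1.35, 1.19 and 1.01 for MEF WT heat shock, KO control and KO heat shock against WT control, and 0.785, 0.818 and 0.578 for mESC in the same order. In the yeast tables the depth could not be read from the values, and no counting interval was computed for any library.

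The counting rule was tested on simulated data made from a library of each of 3 tables with noise of 0.2 log2. It called 87 of 90, 104 of 105 and 103 of 104 genes with a planted change of 1.5 log2, all genes planted at 3, and 0 of 4783, 4389 and 6628 unchanged genes. Every gene was given the same noise, which lies far below 2-fold, so few unchanged genes could have been called. The result checks the rule itself and gives no rate of false calls in these libraries. Of lists of unchanged genes 4, 3 and 3.33 percent fell outside the bound.

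Alternatives were a pseudocount of 0.1 or 10, a larger value of at least 1 or 30, rescaling to a median change of 0 or values as deposited, genes listed at 0 counted, every entry kept, the 15 min library as reference, short RNA and unnamed genes left out, the largest entry per gene in mESC, and the 2-fold rule for NET-seq. For NET-seq, no filter and a mean of at least 10 were tried as well. The pseudocounts, minimum values and rescaling of the mRNA comparisons and the pseudocounts and filters of the NET-seq counts were planned, and the rest, with those for NET-seq lists, were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.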

Results

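Nascent RNA, mRNA and DNA bound by the heat shock transcription factor Hsf1 were profiled in budding yeast and mouse cells, in 38 samples. Nascent RNA was profiled by NET-seq in a yeast strain whose Hsf1 is drawn out of the nucleus by rapamycin (anchor-away, Hsf1-AA), in 4 libraries without rapamycin, 3 at 15 min, 3 at 30 min and 4 at 60 min. The 22 mRNA libraries were single, 1 per group. They covered an Hsf1-AA rapamycin time course, an Hsf1-AA experiment with rapamycin and heat shock alone and together, yeast with analog-sensitive protein kinase A with and without the stress factors Msn2 and Msn4, and wild type (WT) and Hsf1 knockout (KO) mouse embryonic fibroblasts (MEF) and embryonic stem cells (mESC). Chromatin bound by tagged Hsf1 was sequenced in 2 libraries. No file gives read totals, so the number of reads behind each library is unknown. A depth relative to WT control could be read from the low values of the mouse tables only, 1.01 to 1.35 in MEF and 0.578 to 0.818 in mESC. The 10 most abundant genes held between 13.7 and 35.4 percent of the FPKM total in the yeast and MEF mRNA libraries, and between 52.2 and 70.8 percent in the mESC libraries. Changes in mRNA are log2 ratios of FPKM with 1 added, a gene counts as higher or lower at 2-fold or more with a larger value of at least 10, and no difference between mRNA libraries has a replicate check. A gene list is called high or low where its median lay beyond the middle 95 percent of 10000 random lists matched on expression, which is a description of these libraries. In parentheses, a gene carries its log2 change and a list its median log2 change.

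The NET-seq time course asked which genes lose transcription when Hsf1 leaves the nucleus, and within 15 min members of the Hsp70 and Hsp90 systems and of the disaggregase and sequestrase list fell. No strain without the Hsf1 anchor was given rapamycin, in NET-seq or mRNA. Effects of rapamycin itself therefore cannot be told apart from loss of nuclear Hsf1 in any rapamycin comparison. Neither time course has a later library without rapamycin, so time in culture cannot be told apart from rapamycin either. HSF1 itself had a log2 change of -0.10 in the authors' deposited table and was not called. In the authors' deposited table SSA2 and SSA1, cytosolic Hsp70 chaperones, changed by -2.66 and -1.51, and HSP82 and HSC82, the Hsp90 isoforms, by -2.43 and -2.33. The disaggregase gene HSP104 fell by 1.54 in the authors' deposited table, and the aggregate-sorting factors BTN2 and CUR1 changed by -2.04 and -1.58. The transcriptional coactivator gene MBF1 went from a group value of 1046 to 301 in the authors' deposited table.

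By list, 5 of the 12 Hsp70 system genes fell in the authors' deposited table, namely SSA1, SSA2, the J-protein genes SIS1 (-1.95) and YDJ1 (-0.76) and the exchange factor gene FES1 (-1.06). Among the 13 Hsp90 system genes, 6 fell in the authors' deposited table, including the adaptor STI1 (-1.58), the ATPase activators AHA1 (-1.09) and HCH1 (-1.10) and the cyclophilin CPR6 (-0.80). Of the 5 disaggregase and sequestrase genes, 4 fell in the authors' deposited table, HSP42 (-1.23) among them. Among 8 mitochondrial chaperone genes, HSP78 (-1.63) and MDJ1 (-0.74) fell in the authors' deposited table. Besides MBF1, the remaining falls in the authors' deposited table were PSY1 (-3.81), PCD1 (-1.39), RIM4 (-1.30), YKR075C (-1.17), MLH3 (-1.16), TUS1 (-0.86) and LST8 (-0.73), which lies within 2 tested genes of SIS1, and these belong to no list. The 5 genes that rose in the authors' deposited table were PIR3 (0.98), encoding a cell wall protein, the iron uptake genes FET3 (0.88) and SIT1 (0.82), the serine deaminase gene CHA1 (0.74) and the allantoate permease gene DAL5 (0.73). No member of the TRiC and prefoldin, ribosome-associated chaperone, proteasome, Msn2/4 stress response, ribosome biogenesis or ribosomal protein lists was called in the authors' deposited table.

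The authors' deposited table tested 6546 of 7126 genes at 15 min and called 25 as fallen and 5 as risen, each with a q of 0.0297. It gives group values without replicates, so no spread could be computed, and a 2-fold rule on those values in place of the authors' q gave 63 genes.

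**Figure D1:**
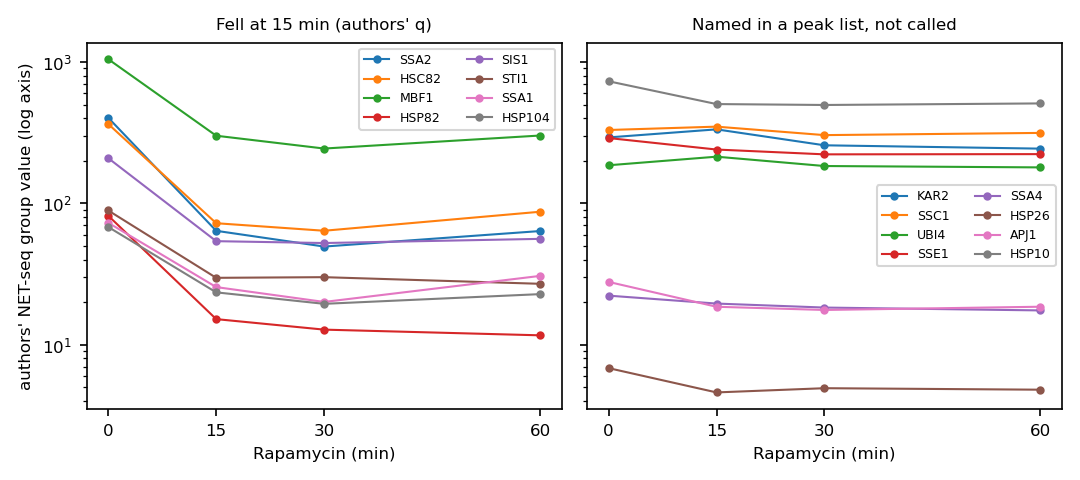
NET-seq group values from the authors' deposited table, on a log axis, against minutes of rapamycin for genes that fell at 15 min (left) and for genes with a peak that were not called (right). SSA2 went from 403 without rapamycin to 63.9 at 15 min and was at 63.7 at 60 min.

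At 30 and 60 min HSC82 and HSP82 stayed far below their 0 min levels. The group values of HSC82 in the authors' deposited table were 364 without rapamycin, 72.3 at 15 min, 64.0 at 30 min and 87.2 at 60 min, and those of HSP82 were 81.7, 15.2, 12.8 and 11.7. PSY1 had a group value of 27.3 at 15 min in the authors' deposited table and of 168 at 60 min. With group values from the authors' deposited table, the Hsp70 system list was low at each time, with medians of -0.22, -0.32 and -0.35, as was the proteasome list, with medians of -0.09, -0.26 and -0.20 and 0, 0 and 0 members 2-fold lower. The nitrogen catabolite repression list, which holds DAL5, was high at each time by the same values of the authors' deposited table, with medians of 0.21, 0.16 and 0.23. The authors' deposited table compares successive times only: DFR1, the dihydrofolate reductase gene, rose from 159.5 to 298 between 15 and 30 min, and between 30 and 60 min FRE4 fell and a gene listed at 0 at 30 min rose. Times of 30 and 60 min were therefore not tested against 0 min, and by the 2-fold rule 14 genes were higher and 45 lower at 30 min, and 19 higher and 51 lower at 60 min (33 in all with a pseudocount of 10).

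Hsf1 binding was described from 39 and 32 peaks, in lists that both carry a heading for basal conditions, so a comparison of heat shock with control was not made. The values are the authors'. SSA1 had the most reads of both lists, with 4299 and 2820 tags in a peak that spans 137505 to 144344 on chromosome I in the larger list. SSA2 (3232 tags), SIS1 (3405), HSP104 (3052), BTN2 (2871), HSP82 (2692) and HSC82 (2395) also ranked among the top 10 of the larger list, as did PMA1 (3892), the plasma membrane proton pump gene. In the smaller list CUP1-1, a metallothionein gene (2770), and UBI4, the polyubiquitin gene (1320), ranked there too. These ranks are by tags and not by fold enrichment. The highest fold enrichment was 19.7 at HSP42 in the larger list and 30.1 at BSC5 in the smaller. It was 10.4 at PMA1 in the larger list, and 6.49 at CUP1-1, the lowest of the smaller list.

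Most genes whose transcription fell were named at a peak. Of the 25 genes that fell in the authors' deposited table, 18 were named in either list, where 0.164 would be expected by their number, and 16 in both, where 0.103 would be. Peaks were matched by the gene name given with each peak, not by position, so the expected numbers give no level for overlap by position. LST8, named at no peak, starts at 620067 on chromosome XIV. That lies within the SIS1 peak of both lists (615859 to 625406 and 617729 to 622320). Peaks also lay at genes without a call in the authors' deposited table, with NET-seq changes of 0.36 at PMA1, 0.16 at the glycolytic gene PGK1, 0.19 at KAR2, the Hsp70 of the endoplasmic reticulum, 0.20 at UBI4, -0.18 at SSA4, an inducible Hsp70, and -0.27 at SSE1, an Hsp110. Every peak had the same score of 3100, which therefore ranks none of them.

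In the mRNA time course the question was how fast mRNA follows. HSF1 mRNA was -0.11 at 15 min, -0.40 at 60 min and 0.02 at 240 min. Some Hsp70 and Hsp90 system mRNAs and HSP104 were lower at 15 and 60 min, with HSP82 at -3.38 and -4.02, SSA2 at -1.17 and -4.49, HSC82 at -1.40 and -3.42, and HSP104 at -1.89 and -2.26. BTN2 (-2.24 and -2.28), SIS1 (-1.88 and -1.73), STI1 (-1.53 and -2.27), MBF1 (-1.15 and -1.56) and HSP78 (-1.48 and -1.80) followed. Of the Hsp70 system, 4 of 9 members were lower at 15 min and 4 at 60 min, with low medians of -0.38 and -0.77. The Hsp90 system had 4 and 6 of 13 lower and the disaggregase and sequestrase list 3 of 3 at both times, with low medians of -0.30 and -2.26 at 60 min. The TRiC and prefoldin list had 0 of 15 members lower at 15 min, and 0 lower and 1 higher at 60 min, and of 6 ribosome-associated chaperones 0 and 0 were lower. The Msn2/4 stress response list was slightly low at 60 min (-0.26), with no member 2-fold different.

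At 240 min the picture was broader, though no library without rapamycin was taken at that time, so effects of time in culture are included. SSA2 stood at -4.52, YDJ1 at -3.69 and HSC82 at -3.05, while HSP82 was at -1.18 and HSP104 at 1.03. Of the Hsp70 system 6 of 10 members were lower and 1 higher, with a low median of -1.81, and of the Hsp90 system 7 of 13 were lower, with a low median of -1.18. The disaggregase and sequestrase list, low at 15 and 60 min, was high (1.47), with 3 of 4 higher and 1 lower. TRiC and prefoldin genes (-0.92, 6 of 15 lower) and ribosome-associated chaperones (-1.69, 4 of 6 lower) were low. The Msn2/4 stress response list was high (2.20, 31 of 34 higher), with HSP12 at 7.62, the catalase gene CTT1 at 4.06 and the phosphoglucomutase gene PGM2 at 4.19. Endoplasmic reticulum folding genes were high (1.31, 8 of 11 higher), with KAR2 at 1.64 and SIL1 at 2.16, and nitrogen catabolite repression genes were high (1.12, 12 of 20 higher), with GAP1, the general amino acid permease, at 3.08 and MEP2, an ammonium permease, at 2.77. Ribosome biogenesis genes were low (-2.72, 45 of 45 lower), with NSR1 at -4.02, the fibrillarin gene NOP1 at -3.40 and the helicase gene DBP2 at -5.55, and 106 of 111 ribosomal protein genes were lower (-1.85). Hexose transporter genes were among the 10 with the lowest changes, HXT2 at -5.03 and HXT1 at -4.81.

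Of 5004 genes at 15 min, 6 were higher and 27 lower, of 5000 at 60 min 15 and 50, and of 5043 at 240 min 640 and 851. All genes shifted by -0.16 at 15 and 60 min, so values there are relative to that shift, and the counts become 9 and 21 at 15 min and 25 and 34 at 60 min once it is taken off. Among genes with values in both assays, 14 of the 21 that fell in the authors' deposited table were lower in mRNA at 15 min, where 0.0841 would be expected, and 15 of 21 at 60 min, where 0.139 would be. The 0 min library stands apart at RPL13A, whose FPKM was 3100.4 at 0 min and 359.9 at 15 min, and at TRP1, with 187 and 848, and against the 15 min library the 60 min count was 29 genes and the TRP1 change -0.013. Every change in this time course is taken against the 0 min library, so chaperone, Msn2/4 and other values at 15, 60 and 240 min could include a difference between strains.

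**Figure D2:**
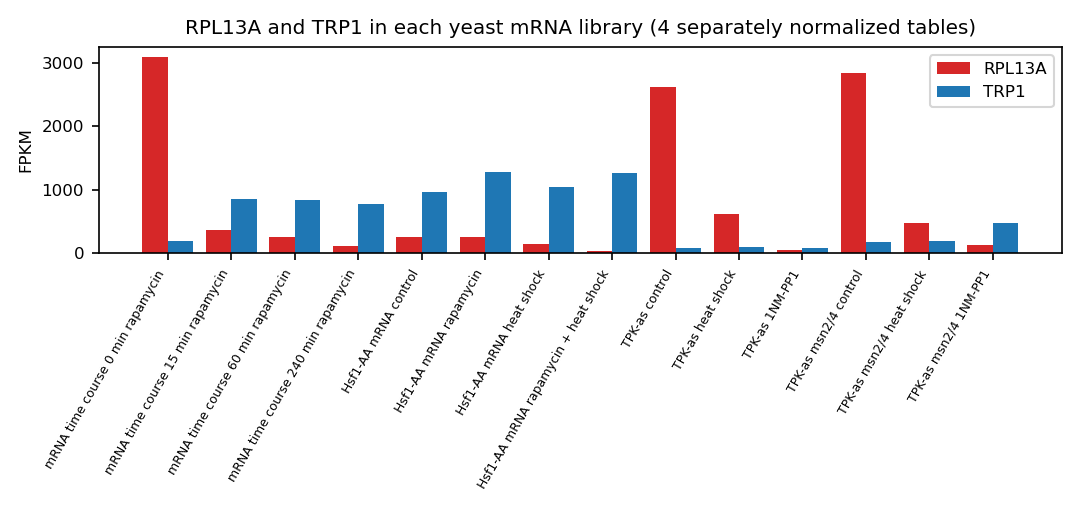
FPKM of RPL13A and TRP1 in each yeast mRNA library, each bar a single library, with an axis from 0. RPL13A was 3100.4 in the 0 min library and 247 in the control library of the separate Hsf1-AA experiment, which was normalized separately.

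The separate Hsf1-AA experiment asked what rapamycin and heat shock do alone and together. HSF1 was -0.29 with rapamycin, 0.48 with heat shock, and 1.59 with both against rapamycin alone. Rapamycin alone left lower levels of SSA2 (-4.57), HSC82 (-3.27), HSP82 (-2.86), STI1 (-2.49), MBF1 (-2.46), SIS1 (-2.37), YDJ1 (-1.84) and HSP104 (-1.23). Of the Hsp70 system 5 of 8 members were lower and of the Hsp90 system 5 of 11, with low medians of -1.26 and -0.96, and 3 of 7 mitochondrial chaperone genes were lower, HSP10 at -1.17 among them. Genes higher with rapamycin included UBC8, a ubiquitin-conjugating enzyme (2.10) and OYE3, an old yellow enzyme (1.89). The Msn2/4 stress response list was high (0.45, 2 of 36 higher), where it was at -0.26 at 60 min in the time course. Ribosome biogenesis was low (-0.39, 0 of 44 lower). Of 4600 genes 62 were higher and 43 lower with rapamycin, a total of 105 that became 67 with a pseudocount of 10 and 437 with every table entry kept. Of 20 genes that fell in the authors' deposited table, 13 were lower here, where 0.183 would be expected.

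With heat shock alone, small heat shock protein, disaggregase and general stress genes were higher, and chaperone lists differed. HSP26 (9.21) and HSP42 (4.01), the small heat shock proteins, SSA4 (6.15), HSP82 (3.55), HSP104 (3.31), HSP78 (3.49) and HSP30 (7.13), a plasma membrane protein, were higher. All 4 measured members of the disaggregase and sequestrase list were higher, with a high median of 3.66. The Hsp70 system had 3 of 9 higher and 1 lower (-0.03) and the Hsp90 system 5 of 11 higher and 1 lower (0.67), both within the middle 95 percent. TRiC and prefoldin genes were low (-0.81, 5 of 15 lower), as were ribosome-associated chaperones (-1.55, 4 of 4 lower). Of the Msn2/4 stress response 35 of 36 were higher (2.69), with HSP12 at 7.90, CTT1 at 3.87 and the trehalose synthase gene TPS1 at 2.62. Ribosome biogenesis was low (-2.42, 41 of 44 lower), with NSR1 at -4.29 and DBP2 at -6.05, as were ribosomal protein genes (-1.36, 88 of 111 lower). In all 621 genes were higher and 832 lower of 4630.

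After rapamycin, small heat shock protein, HSP104 and general stress genes were again higher with heat shock. Relative to rapamycin alone, HSP26 was at 7.28, HSP42 at 5.19, HSP82 at 4.46 and HSP104 at 3.95, and 35 of 36 Msn2/4 stress response genes were higher (2.81). SSA4 was at 2.87, and YDJ1 and SSE1 stood lower, at -2.44 and -2.69. TRiC and prefoldin genes were low (-1.39, 13 of 15 lower), and 4 of 4 ribosome-associated chaperones were lower (-2.24). In this comparison 836 genes were higher and 1161 lower of 4620. As the difference between both heat shock responses, with rapamycin minus without, SSA4 was -3.28, CPR6 -2.20, SSE1 -2.34, SIS1 1.45 and HSP82 0.90. By that difference the Hsp70 system was low (-0.87, 4 of 9 lower and 2 higher), ribosome biogenesis was low (-1.74), 106 of 111 ribosomal protein genes were lower (-2.99), with RPS3 at -3.80, and endoplasmic reticulum folding genes were high (0.83), with KAR2 at 1.59. It reached 2-fold for 163 genes upward and 476 downward, and each rests on 4 single libraries with no test of the difference. The positive differences of SIS1 and HSP82 start from levels with rapamycin alone that were below control, as given above. For both genes the fall with rapamycin alone was larger than the positive difference. Their levels with both treatments therefore lay below those of heat shock alone, in single libraries.

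**Figure D3:**
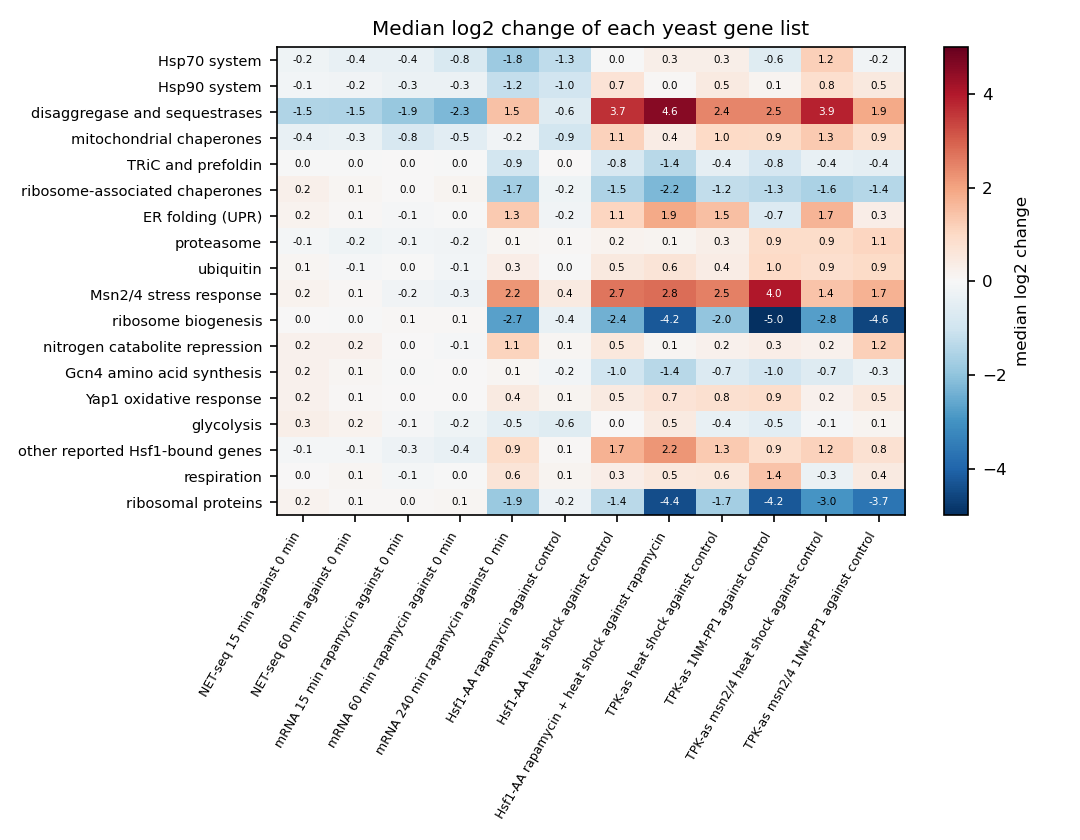
Median log2 change of each yeast gene list at 15 and 60 min in NET-seq and in each mRNA comparison, shown as colour and as a printed value. The Msn2/4 stress response list was at 2.69 with heat shock in Hsf1-AA, 3.99 with 1NM-PP1 in TPK-as and 1.72 with 1NM-PP1 in the strain without Msn2 and Msn4.

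In the TPK-as strain TPK1, TPK2 and TPK3, the catalytic subunits of protein kinase A, accept the inhibitor 1NM-PP1, and heat shock was set beside that inhibition. TPK1 was at 36.0 FPKM in control, 78.8 in heat shock and 113 with 1NM-PP1, TPK2 at 34.5, 62.1 and 81.3, and TPK3 at 67.7, 25.9 and 13.3. MSN2 and MSN4 were at 33.3 and 47.1 FPKM in control. General stress genes were higher in both, HSP12 at 7.10 with heat shock and 8.14 with 1NM-PP1, HSP26 at 7.59 and 6.76, CTT1 at 3.10 and 6.83, and PGM2 at 3.70 and 5.30. Among chaperones of the Hsp70 and Hsp90 systems, SSA4 was at 4.92 and 3.15, HSP82 at 2.62 and 1.30, STI1 at 1.56 and 0.84, SSA2 at -0.49 and -2.23, and YDJ1 at 0.32 and -1.99. Both lists lay within the middle 95 percent in both treatments, the Hsp70 system at 0.29 and -0.60 and the Hsp90 system at 0.47 and 0.15. Ribosome-associated chaperones were low in both (-1.23 and -1.34, 3 of 6 lower in each), and TRiC and prefoldin genes with 1NM-PP1 (-0.82, 4 of 15 lower).

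Of 34 Msn2/4 stress response genes 32 were higher in heat shock (2.52) and 33 with 1NM-PP1 (3.99). Endoplasmic reticulum folding genes were high as a list in heat shock, with 9 of 11 higher, KAR2 at 1.83 and SIL1 at 2.20, while with 1NM-PP1 the list lay within the middle 95 percent (-0.67, 3 of 11 lower), KAR2 at -1.46 and SIL1 at -1.10. Respiration genes were high in heat shock (0.57, 8 of 32 higher and 1 lower) and with 1NM-PP1 (1.44, 26 higher and 1 lower), with the succinate dehydrogenase gene SDH2 at 1.56 and 2.79. Ribosome biogenesis was low in both (-1.99 and -4.98), with NSR1 at -2.74 and -7.43, and ribosomal protein genes were low (-1.71 and -4.24, 96 and 111 of 111 lower), with RPL3 at -2.17 and -5.93. Of 5024 genes 556 were higher and 716 lower in heat shock, and of 5006 with 1NM-PP1 844 and 1228. With 1NM-PP1 all genes shifted by -0.12, and values there are relative to that shift.

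Without Msn2 and Msn4 the same treatments were compared again. In the heat shock library of that strain MSN2 was at 0.278 FPKM and MSN4 at 0.0448, and in its control TPK1 was at 17.2. With heat shock stress-inducible chaperone genes were higher, SSA4 at 7.51, HSP26 at 6.58, HSP42 at 4.19, HSP104 at 3.52, HSP82 at 3.45, CPR6 at 3.44 and STI1 at 2.48. Of the Hsp70 system 6 of 10 were higher and 1 lower (1.21), of the Hsp90 system 5 of 13 (0.83), and of endoplasmic reticulum folding genes 10 of 11 (1.71), with ERO1 at 2.93. Ribosome-associated chaperones were low (-1.58, 5 of 6 lower), and of 15 TRiC and prefoldin genes 1 was higher and 0 lower (-0.37, within the middle 95 percent). Of the Msn2/4 stress response 22 of 32 were higher (1.42), with HSP12 at 4.95, while CTT1 was at 0.95. SIP18, which is not on that list, was at 0.52. With 1NM-PP1 31 of 34 Msn2/4 stress response genes were higher (1.72), among them GLK1, a glucokinase gene (3.67), and CYC7, a cytochrome c gene (4.06). Proteasome genes were high with heat shock (0.92, 7 of 32 higher) and with 1NM-PP1 (1.09, 18 higher). Nitrogen catabolite repression genes were high with 1NM-PP1 (1.19), with MEP2 at 3.17, and within the middle 95 percent with heat shock (0.20). Ribosome biogenesis was low in both (-2.75 and -4.61), with NSR1 at -3.81 and -7.13.

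Set against the TPK-as strain, in separately normalized tables, the Msn2/4 stress response was lower in both responses. The difference had a low median of -1.29 for heat shock, with 20 of 34 lower and 1 higher, and of -1.94 for 1NM-PP1, with 26 of 34 lower and 1 higher. For HSP12 the differences were -2.15 and -5.67, for CTT1 -2.15 and -5.66, and for FMP45, which is not on the list, -4.88 and -6.99. Chaperone lists were high in the heat shock difference, the Hsp70 system at 0.58, the Hsp90 system at 0.56 and the disaggregases and sequestrases at 1.41, with SSA4 at 2.59 and BTN2 at 2.41. Respiration genes were low in both differences (-0.87 and -1.14). All genes shifted by 0.21 in both comparisons of the strain without Msn2 and Msn4, so its values are relative to that shift. Its counts were 796 higher and 686 lower of 5015 in heat shock (551 and 828 once the shift is taken off) and 890 and 715 of 4996 with 1NM-PP1 (629 and 830), and the differences reached 2-fold for 84 genes upward and 367 downward in heat shock and 369 and 408 with 1NM-PP1, none of them tested.

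In fibroblasts the inducible Hsp70 genes and several of their cochaperones were higher with heat shock in WT, and in Hsf1 KO none of the Hsp70 system passed 2-fold. Hsf1 was at 32.2 FPKM in WT control and at 35.7 in KO control, so this table shows no loss of its mRNA. The inducible Hsp70 genes Hspa1a and Hspa1b were at 5.80 and 5.92 in WT and at -0.26 and -0.17 in KO. The J-protein genes Dnajb1 (2.88 in WT and -0.09 in KO), Dnaja1 (2.65 and 0.07) and Dnajb4 (2.63 and 0.13), the Hsp110 gene Hsph1 (2.87 and 0.37) and the cochaperone gene Bag3 (1.87 and -0.07) went the same way. Hsp90aa1, the inducible Hsp90, was at 1.03 and 0.02, Hspa8, the constitutive Hsp70, at 0.71 and 0.15, the small heat shock protein gene Hspb8 at 1.30 and 0.06, and Serpinh1, the collagen chaperone, at 1.01 and 0.08.

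Of the Hsp70 system 9 of 21 were higher in WT (0.53) and 0 of 18 in KO, and the Hsp90 system was high in WT (0.57, 1 of 15 higher). Of TRiC and prefoldin 0 of 13 were higher and 1 lower in WT, though the list was high by its small median of 0.06. As a difference, KO minus WT, the Hsp70 system (-0.47, 8 of 20 lower), the Hsp90 system (-0.53) and the small Hsps (-0.57, 2 of 4 lower) were low. Immediate early genes were high in both genotypes, 6 of 15 higher in WT (0.77) and 12 of 17 in KO (1.33), with Atf3 at 2.99 and 1.17, the phosphatase gene Dusp1 at 1.14 and 2.28, Myc at 1.01 and 1.88, and Junb at 0.41 and 1.62. Ubc, a polyubiquitin gene, was at 1.20 and 0.72 and the arsenite-inducible gene Zfand2a at 1.55 and 0.75. Without heat, KO minus WT, Hspa8 was at -0.55, Hsp90aa1 at -0.50, Hsph1 at -0.54 and Fkbp4, an Hsp90 cochaperone, at -0.85, none of them 2-fold lower. The Hsp70 system (-0.19), the Hsp90 system (-0.28) and the small Hsps (0.42) all lay within the middle 95 percent there, with no member 2-fold different. Of the fibroblast list 3 of 19 genes were higher, the smooth muscle actin gene Acta2 at 1.58, Lox at 1.55 and Fn1 at 1.05.

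In WT 65 genes were higher and 35 lower of 6971, in KO 107 and 29 of 7255, and in KO control against WT control 127 and 92 of 7232, with the heat shock difference at 2-fold for 63 upward and 54 downward, untested. The totals of 100, 136 and 219 became 58, 71 and 96 with a pseudocount of 10, and counting genes listed at 0 in a library made the WT and KO totals 164 and 211. At a larger value of at least 30 the last 2 totals were 89 and 107, and at a value of at least 1 the last was 381. No macrophage, epithelial or endothelial gene reached the value of 10 in any comparison.

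**Figure D4:**
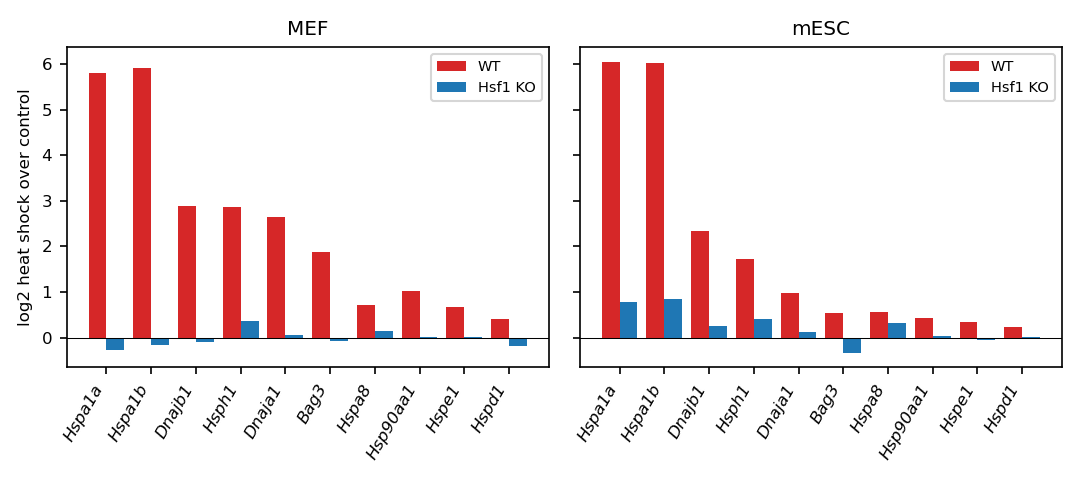
Log2 change with heat shock of chaperone genes in WT and Hsf1 KO MEF and mESC, each bar a pair of single libraries. Hspa1a was at 5.80 in WT MEF, -0.26 in KO MEF, 6.05 in WT mESC and 0.78 in KO mESC, from separately normalized tables for MEF and mESC.

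In stem cells the inducible Hsp70 genes were again higher with heat shock in WT. Hsf1 was at 13.6 FPKM in WT control and 0.114 in KO control. Hspa1a and Hspa1b were at 6.05 and 6.01 in WT and at 0.78 and 0.85 in KO, Dnajb1 at 2.35 and 0.26, and Hsph1 at 1.72 and 0.41. Dnaja1 was at 0.97 and 0.13, Hspa8 at 0.56 and 0.33, Chordc1, an Hsp90 cochaperone, at 0.60 and 0.18, and Fkbp4 at 0.50 and 0.49. The genes Rps20 (6.27 and 6.25), Madd (4.57 and 5.07), Gas5 (4.26 and 5.02) and Clk1 (4.14 and 4.41), a splicing kinase gene, were higher in both genotypes. With Hyou1 and Dnmt3l, they belong to 41 genes higher by at least 1.5 log2 in both, of which the 37 in the MEF table had a median of -1.96 log2 in mESC WT control against MEF WT control, across separately normalized tables.

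Of the Hsp70 system 4 of 17 were higher in WT (0.22) and 0 of 14 in KO, and the Hsp90 system was high in WT (0.21) with 0 of 15 at 2-fold. Endoplasmic reticulum folding genes were high in both (0.30 and 0.26, 2 of 18 higher in each), Hyou1 at 2.17 and 2.54 and Herpud1 at 1.40 and 1.67. The pluripotency list was low in WT (-0.24), with Fgf4 at -1.03 and Dnmt3l, a regulator of DNA methylation, at 2.31. As a difference, KO minus WT, the Hsp90 system was low (-0.18, 0 of 15 lower), as were the small Hsps (-0.26, 2 of 5 lower). The Hsp70 system lay within the middle 95 percent (-0.04), with 4 of 17 lower, Hspa1a at -5.27 and Dnajb1 at -2.09. Without heat, KO minus WT, the small Hsps were high (0.90, 2 of 5 higher), with Hspb8 at 1.09 and Hspb11 at 1.77, and Fkbp4 was at -1.05. In the same comparison the smooth muscle gene Tagln was at 1.72 and the keratin gene Krt18 at 1.13. The early lineage differentiation list, which holds Krt18, was low there (-0.23, 1 of 7 higher). Pluripotency genes were low as a list as well (-0.22), with none 2-fold lower. Of the macrophage list Cd68 alone reached the value of 10.

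In WT 145 genes were higher and 80 lower of 8329, in KO 269 and 115 of 8352, and in KO control against WT control 59 and 53 of 8224, with the heat shock difference at 2-fold for 119 upward and 79 downward, untested. Without short RNA and unnamed genes the totals of 225, 384 and 112 became 118, 174 and 29, and with the largest table entry of each gene in place of the sum the heat shock totals were 681 and 920. With a pseudocount of 10 the totals were 117, 193 and 47, with a larger value of at least 30 they were 123, 229 and 53, and of at least 1 they were 363, 605 and 193.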

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

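The following genes stood out because they were at least 2-fold higher in a comparison and at least 2-fold lower in the matching comparison of the other strain or genotype. The differences were not tested, and each rests on single libraries. With 1NM-PP1, YAR068W had a log2 change of -1.25 in TPK-as and 1.47 in TPK-as msn2/4. ARO5 went the same way, at -1.26 and 1.40, and YER175W-A the other way, at 1.28 and -1.32. With heat shock, Mmp11, a matrix metalloproteinase gene, was at -1.58 in WT MEF and 1.42 in Hsf1 KO MEF.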

How the results depend on the processing

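Of the results that answer a comparison, 160 values under an alternative stayed within 1.5 times the main value and 28 moved further. Among the other counts and named values 256 stayed, 50 moved and 4 reversed, and of single list calls 2034 stayed, 24 were lost, 22 were gained and 3 reversed. The cause was not tested except where a setting itself adds or removes genes. With a pseudocount of 10 the number of genes was 67 for Hsf1-AA rapamycin, 58, 71 and 96 for MEF WT heat shock, KO heat shock and KO control against WT control, 117, 193 and 47 for the same in mESC, and 33 for NET-seq at 60 min. With a larger value of at least 1 it was 381 for MEF KO control, with 5 lists beyond the middle 95 percent, and 363, 605 and 193 for mESC, and with at least 30 it was 89 and 107 for MEF KO heat shock and KO control and 123, 229 and 53 for mESC. Alternatives chosen after seeing the data gave 29 for 60 min rapamycin against the 15 min library, 437 for Hsf1-AA rapamycin with every entry kept, 164 and 211 for MEF WT and KO heat shock with genes listed at 0 counted, 118, 174 and 29 for mESC without short RNA and unnamed genes, 681 and 920 for mESC WT and KO heat shock with the largest entry per gene, and 63 for NET-seq at 15 min by the 2-fold rule. Values that reversed were the ribosomal protein median at 15 min, -0.11 with values as deposited, the mitochondrial chaperone median and TRP1 at 60 min, 0.091 and -0.013 against the 15 min library, and the early lineage median in mESC KO control, 0.91 with at least 30.

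No paired analysis was possible because the deposited NET-seq table gives group values only. For the same reason other normalizations and tools, a test of lists with an estimated correlation, fewer samples in the fit, the replicate block and leaving out replicates were not run, nor were pseudocounts for the authors' calls at 15 min, and no splits of samples were possible. ChIP-seq alternatives were not run because neither list is assigned to heat shock. The unknown number of reads limits genes near the value of 10, whose 2-fold differences may rest on few reads, and with a larger value of at least 30, which also compares fewer genes, the mESC WT count was 123.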

Other observations

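All tests in this part were chosen after the results were seen. The strains differ in mating-type genes, given here across separately normalized tables. STE3, the a-factor receptor gene of alpha cells, was at 1819 FPKM in the Hsf1-AA time course without rapamycin and at 14.2 in the TPK-as control. STE2, the alpha-factor receptor gene of a cells, was at 19.2 and 487, and MFA2, an a-factor gene, at 122 and 13337. FPR1, the rapamycin-binding protein gene, was listed at 0 throughout the time course and was at 946 in the TPK-as control. In the separate Hsf1-AA experiment the pheromone gene MF(ALPHA)1 was at 938 in control, 800.1 with rapamycin, 176 with heat shock and 5.08 with both, and MF(ALPHA)2 at 782, 924, 48.8 and 35.2.

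In stem cells without heat, KO minus WT, Phlda2 was at -1.91, Grb10 at -1.76, Cdkn1c at -1.49, Dlk1 at 1.17, Meg3 at 1.17 and Igf2 at 1.16. These genes were picked after their values were seen. Dppa3, a germ line and pluripotency gene, was at 1.44. In fibroblasts H19 was at -2.17 and Afp, the alpha-fetoprotein gene, at 2.40.

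RPL13A was far higher and TRP1 lower in the 0 min library than in every later library of the time course. RPL13A changed by -0.0045 log2 with rapamycin in the separate Hsf1-AA experiment. It was already at 247 FPKM in the control there, so that change cannot decide on a response to rapamycin. In NET-seq the authors' group values of RPL13A were 461, 537, 484 and 483 at 0, 15, 30 and 60 min, so its transcription did not fall. Reads shared with its paralog RPL13B are argued against by RPL13B, which was lower at 15 min than at 0 min by a difference of -317 FPKM. A 0 min library from cells without a tag at RPL13A may account for the pattern, since RPL13A was at -3.64 log2 in the untreated library of the separate experiment against the 0 min library, across separately normalized tables. No biological explanation was tested beyond rapamycin.

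In mESC 41 genes, among them Rps20, Madd, Gas5, Clk1 and Hyou1, were higher with heat shock in both genotypes and 2 lower, by at least 1.5 log2. Over the 28 with a MEF WT control value of at least 10, the median change in MEF WT heat shock was 0.013 log2, which argues against a heat response shared with fibroblasts for these genes as a set. It stays open for 4 of them, Clk1, Clk4, Dpp7 and D4Wsu53e, which were at least 0.5 log2 higher there, where 95 percent of random sets have at most 2. Over all 37 in the MEF table, across separately normalized tables, the median against MEF WT control was -1.96 log2 in mESC WT control, where 95 percent of sets matched on level lay between -0.75 and 0.28, and 0.56 in mESC WT heat shock, between -0.20 and 0.62. The 37 genes were selected for mESC control values below heat shock, and the matched sets were not, so the selection itself favours a low control median. The comparison therefore cannot decide whether reads of the control libraries were assigned elsewhere. Of the 37, 4 were above MEF in control, Dnmt3a, Dnmt3l, Ptprf and Tle4. A response of stem cells alone stays open, as untested.

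PSY1, PCD1, RIM4, YKR075C, MLH3, TUS1 and LST8 fell in NET-seq at 15 min in the authors' deposited table without being named at a peak of Hsf1. By position LST8 starts within the SIS1 peak of both lists, so it lacks a peak by name only. Reads running on from a neighbouring Hsf1 gene are argued against as a general cause, since 1 of the 7, LST8 next to SIS1, lay within 2 tested genes of a gene that fell with a peak, a number that 95 percent of random sets do not exceed. The count of neighbours took no account of strand, and the identifiers of SIS1 (YNL007C) and LST8 (YNL006W) place them on opposite strands. Reads running on from SIS1 would therefore not lie on the strand of LST8. Whether reads were counted by strand was not checked. A fall in mRNA was not seen either, with 0 of the 4 genes that have a value at least 2-fold lower with rapamycin in the separate Hsf1-AA experiment. Whether the binding at the SIS1 peak acts on LST8 was not tested, nor was binding below the threshold of the peak lists at the other genes.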
